A study of Mus musculus with 6 samples.

How the data were processed

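Libraries of non-small cell lung cancer cells from mouse tumours were compared, 2 mRNA libraries of Dicer1 heterozygous and 2 of Dicer1 knockout cells and 1 small RNA library of each. Per the labels' protocols, cells were grown in DMEM with fetal bovine serum, total RNA was extracted with Trizol, and mRNA libraries were made with an Illumina TruSeq kit and small RNA libraries with an NEBNext kit. Groups and replicate numbers were taken from the sample titles and genotypes.

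The authors deposited gene values as FPKM, fragments scaled to gene model length and to mapped fragments, per the file headers, for 21881 genes on mouse build mm9. TopHat 1.3 and Cufflinks 2.0.3 are named in the submitters' processing notes, without their roles. The annotation, the filters and the treatment of reads that map to several places are not given in the sources used here. The same deposited table carries the authors' unadjusted p-value for each of 16735 genes and the authors' log2 fold change. All of those p-values (100%) lay within 0.0001 of a Welch test on the FPKM. The small RNA tables the authors deposited hold whole numbers for 335 mature miRNAs and 848 hairpins, treated as a score because their names say RPM and their headers say reads. No count model was used on them, and the aligner, miRNA annotation and total are not given in the sources used here.

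FPKM has no counts, so depth enters only as a ratio. Among genes under 0.15 FPKM in both libraries of a pair, ratios piled up at 1 value, held by 18.2% to 23.3% of genes within 0.05 on the log2 scale, and this value was taken as the relative depth. An exact 0 in the FPKM table can be a failed estimate, since Ndufs5, a subunit of complex I (chosen after its values were seen), was listed at 0 in both heterozygous libraries against 6.69 FPKM in knockout replicate 2. Such genes are given as listed at 0, with no fold change against a group at 0. Of 10937 tested genes, 204 were listed at 0 in at least 1 library, and 80 of these changed.

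Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the prior variance, over genes with a mean of at least 1 FPKM over the 4 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 change is on the log2(FPKM + 1) scale, which understates the change of low genes, and a fold is the ratio of mean FPKM. Errors of FPKM are the SD over 2 libraries and errors of log2 changes are SE. The tests, the filter, the rule for named genes and 39 lists of genes for pathways, cell types and miRNA targets were fixed before the data were examined. Of their 1128 entries, 1122 matched to a gene of the table by symbol or by a synonym of the GRCm38.p6 gene table. The 35 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over these lists. An estimated correlation leaves camera the 2 residual degrees of freedom of 4 libraries, so a call lost with it says little by itself. Where the estimate lies far above the preset value, the call rests on that preset value. Genes of a list were also adjusted over the list alone. Named genes were 7 chosen in advance, the 10 largest rises and the 10 largest falls past the threshold without small or unnamed gene models, and up to 4 changed genes with the largest change per list. Named miRNAs were the 10 highest in the heterozygous library, those with the largest and smallest ratios among miRNAs with at least 100 in either library, and preset families. For small RNAs, with 1 library per genotype, no test was made, and intervals of shares are 95% Clopper-Pearson intervals.

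The limma and camera steps were tested on simulated data for the knockout against heterozygous mRNA comparison, with 10937 genes and 2 libraries per genotype. There 6% of 100 genes changed 2-fold and 80% of 100 genes changed 4-fold were recovered. Of the calls, 6.52% were unchanged genes, and no change simulated gave 0 calls. A shifted list was called, and 0 of 38 unshifted lists were. Simulated genes varied independently of each other and with the same variance in both genotypes. In the data the estimated correlation between genes was 0.32 for HIF target genes and 0.63 for cytosolic ribosomal proteins. The simulation therefore does not show how often lists of correlated genes are called. Its rates hold only for the simulated variance and the simulated number of changed genes. More called genes make the Benjamini-Hochberg limit laxer, and 1551 genes were called in the data, so the recovery there is not known from it. Alternatives were other pseudocounts, filters, scalings, prior variances, list tests, leaving out each library and the replicate number as a block. Libraries correlated across genes at 0.967 within heterozygous and 0.913 within knockout cells, against 0.849 to 0.883 between genotypes, and genes are not independent replicates. The median absolute log2 difference between replicates was 0.17 in heterozygous and 0.32 in knockout libraries. Figures were drawn with matplotlib 3.10.9. The effect of sites in 3' UTRs was not analysed here.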

Results

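Loss of Dicer1, the RNase III enzyme that cuts miRNA hairpins into mature miRNAs, was examined in cultured non-small cell lung cancer cells of the mouse. The cells had been derived from lung tumours driven by an activated Kras allele in animals without p53. Polyadenylated RNA was sequenced from 2 libraries of Dicer1 heterozygous cells and 2 libraries of Dicer1 knockout cells, and small RNA from 1 library of each genotype. The labels give 1 line code for all heterozygous libraries and 1 other for all knockout libraries, so genotype and cell line were not separable. The series record calls the replicates biological, without saying whether they were separate cultures of that line, so p-values measure only the spread between these libraries. Among genes of low FPKM, 18.2% to 23.3% shared 1 ratio between the libraries of a pair, which was taken as the relative depth. These ratios put knockout replicate 2 at 1.27 times, knockout replicate 1 at 1.06 times and heterozygous replicate 2 at 0.887 times the depth of heterozygous replicate 1. The absolute depth was not known for any library. In knockout replicate 2, gene models of small RNAs (symbols starting with Mir, Snor, Scarna or Rnu) took 18.5% of the FPKM sum. They took 2.60% to 4.33% in the other 3 mRNA libraries, and Snord2 alone took 8.48% in knockout replicate 2.

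The first question was whether the libraries carry the loss of Dicer1 that their labels give. Dicer1 mRNA stood at 4.47 and 5.66 FPKM in the heterozygous libraries and at 2.48 and 3.72 FPKM in the knockout libraries, a log2 change of -0.58 ± 0.25 (SE). This did not pass the threshold (limma adjusted p = 0.177). The value covers the gene as a whole and does not check a deletion that removes part of the transcript. The mature miRNAs differed far more. Their deposited values summed to 75513 in the heterozygous library and 293 in the knockout library, 258-fold lower. All 52 mature miRNAs with at least 100 in the heterozygous library were at least 4-fold lower in the knockout library (100%, 95% Clopper-Pearson interval 93.2% to 100%), and 30 of the 52 were listed at 0 there. Over all 335 mature miRNAs, 290 were lower and 12 higher in the knockout library, the others being equal. miR-21a-5p, the highest miRNA of the heterozygous library, stood at 24661 against 114, miR-182-5p at 7994 against 39 and let-7f-5p at 5461 against 5. Next came let-7i-5p at 3356 against 4, miR-30a-5p at 2805 against 1, let-7c-5p at 2137 against 3, let-7g-5p at 2032 against 3 and miR-7a-5p at 1460 against 6. miR-99b-5p at 2006 and miR-25-3p at 1713 in the heterozygous library were both listed at 0 in the knockout library. The preset let-7 group, let-7a to let-7g, let-7i and miR-98, miRNAs that repress growth-promoting mRNAs, summed to 14542 against 19. Sums were 1099 against 0 for the miR-17~92 cluster, 2162 against 0 for the miR-106b~25 cluster, 483 against 0 for the miR-29 family, 108 against 0 for the miR-200 family and 44 against 0 for the miR-34 family. Among the 52 miRNAs with at least 100 in the heterozygous library, the largest share was left for miR-532-5p, at 770 against 17 (2.21%). After it came miR-221-5p at 1055 against 19 (1.80%), miR-30c-5p at 177 against 3 (1.69%), miR-27a-5p at 504 against 8 (1.59%) and miR-183-5p at 1087 against 13 (1.20%). With 1 library per genotype these differences have no replicate check. The interval treats miRNAs as independent draws and covers no error of the values themselves, and the total that the values are relative to is not known.

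**Figure D1:**
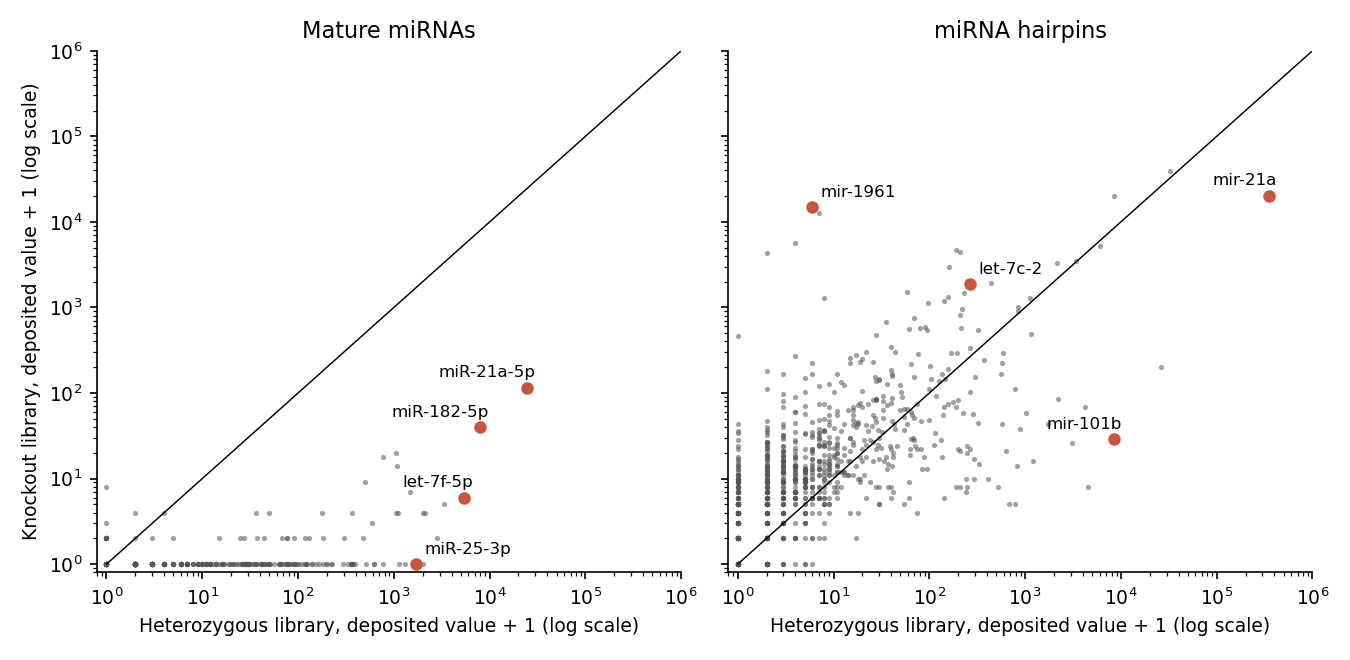
Deposited values of each mature miRNA (left) and each miRNA hairpin (right) in the knockout library against the heterozygous library, 1 point per miRNA, each value plus 1 on log scales, with a line of equal values. Every mature miRNA with at least 100 in the heterozygous library lies below the line, miR-21a-5p at 24661 against 114, while hairpins lie on both sides, mir-1961 at 5 against 14726.

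Deposited values of hairpins, the precursors that Dicer1 cuts, went both ways. They cannot be read as amounts of uncut precursor, since how reads were assigned to them is not given. In the heterozygous library mir-21a stood at 347686, against 24661 for mature miR-21a-5p. Of 83 hairpins with at least 100 in the heterozygous library, 38 were at least 4-fold lower in the knockout library (45.8%, 95% Clopper-Pearson interval 34.8% to 57.1%), and 28 were higher there. Over all 848 hairpins, 604 were higher and 190 lower in the knockout library, the others being equal. Only 83 of the 848 reached 100 in the heterozygous library and 92 in the knockout library, so most rows held low values. Each value is relative to a total that is not known. The hairpin sum was 482932 in the heterozygous library and 186188 in the knockout library, and mir-21a alone made up 347686 and 20317 of these. Without mir-21a the sums were 135246 and 165871. The lowest ratios were those of mir-7a-2 at 4496 against 7, mir-101b at 8432 against 28, mir-320 at 786 against 4, mir-23a at 679 against 4 and mir-30a at 26069 against 198. The highest ratios belonged to mir-344d-2 at 1 against 4376, mir-1961 at 5 against 14726, mir-6348 at 6 against 12695 and mir-1186a at 3 against 5665, and mir-669d was listed at 0 against 459. Hairpins of the preset let-7 group were higher in 9 of 12 cases and summed to 1490 against 4250, opposite to their mature miRNAs. Outside this group, let-7j stood at 60 against 8 and let-7k at 2 against 79. Hairpins of the miR-17~92 cluster summed to 2791 against 163, those of the miR-106b~25 cluster to 1178 against 361, those of the miR-29 family to 296 against 123 and those of the miR-200 family to 431 against 60. Mature miRNAs of the preset group that Drosha does not make summed to 427 against 0, and their hairpins to 1079 against 49. Hairpin sums were 19 against 67 for the miR-34 family, 45 against 74 for the miR-290 cluster and 14 against 101 for miRNAs of blood and other tissues. mir-451a, whose maturation does not need Dicer1, stood at 0 against 8. How reads were divided between the hairpin table and the mature table is not given in the sources used here. The share of hairpins lower depended on the minimum value, from 21.3% with a minimum of 10 to 58.8% with a minimum of 1000.

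The second question was which mRNAs differ between knockout and heterozygous cells. Some genes known from liver and endoderm were among the largest increases. This was read from the top of the ranking, since no list of liver genes was tested. Of 20 genes abundant in liver, 6 reached 1 FPKM in the knockout mean and 0 in the heterozygous mean. Tm4sf1, a tetraspanin-like surface protein, rose from 3.43 ± 0.587 to 686 ± 30.5 FPKM (SD, n = 2), and some transcripts of lipoproteins and plasma proteins followed. Afp, the fetal counterpart of albumin, rose from 3.39 ± 0.101 to 275 ± 33.5 FPKM (log2 change 5.97 ± 0.19 SE, limma adjusted p = 0.000178). Apob, the structural protein of low-density lipoprotein, rose from 0.6303 ± 0.0601 to 86.5 ± 13.2 FPKM. Apoc2 rose from 0.542 ± 0.365 to 228 ± 88.2 FPKM, and Ttr, a carrier of thyroxine, from 0.0936 ± 0.0369 to 28.01 ± 1.75 FPKM. Alb was listed at 0 in both heterozygous libraries and stood at 33.2 and 35.7 FPKM in the knockout libraries. Fgb, a chain of fibrinogen, was listed at 0 in both against 28.2 and 28.00 FPKM. Ddc, which makes dopamine and serotonin, was listed at 0 and 0.235 FPKM against 40.6 and 32.9 FPKM. The galectin Lgals2 rose from 3.06 ± 1.85 to 262 ± 51.7 FPKM, and Lgals6 from 3.14 ± 0.968 to 148 ± 58.9 FPKM. Lgals6 is nearly identical to Lgals4 and its reads are uncertain. Among the largest decreases, Cldn6, a tight junction claudin, fell from 87.4 ± 6.67 to 1.29 ± 0.223 FPKM. Krt7, a keratin of simple epithelia, fell from 866 ± 67.5 to 32.6 ± 14.1 FPKM, and Spp1, secreted osteopontin, from 2568 ± 142 to 111 ± 0.00495 FPKM. Pkp1, a desmosome protein, stood at 18.7 and 16.8 FPKM and was listed at 0 in both knockout libraries. Aqp1, a water channel, was 76.2-fold lower and Ifitm3, an antiviral membrane protein, 23.3-fold lower. Mcpt1 was 36.8-fold, Syt8 39.96-fold, Lsp1 37.9-fold and Fmnl1 18.9-fold lower. Each of these 20 genes stayed past the threshold without any single library. Of 10937 tested genes, 1551 changed at a limma adjusted p under 0.05, 832 higher and 719 lower in the knockout. The balance turned to 788 higher and 917 lower with median centring, 808 and 813 with quantile normalization and 522 and 549 with no filter on low values. It also turned without heterozygous replicate 1 (149 of 290 lower), heterozygous replicate 2 (161 of 299 lower) and knockout replicate 1 (988 of 1869 lower). Of the 1551, 1224 changed by at least 2-fold. The count was 290 without heterozygous replicate 1, with 276 of the 1551 genes among them, and 299 without heterozygous replicate 2, with 288 among them. The authors' deposited table lists 1414 genes at an unadjusted p under 0.05. Of its p-values for the genes tested here, 0 stayed under 0.05 after Benjamini-Hochberg adjustment. Of the 1129 among them tested here, 671 also changed here, all in the same direction.

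**Figure D2:**
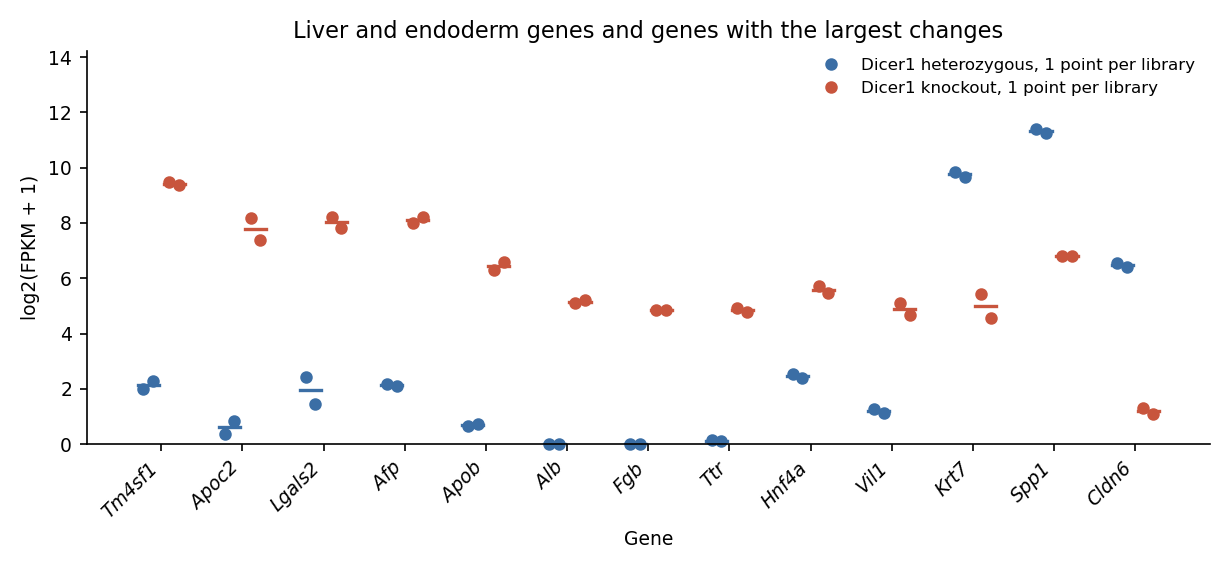
FPKM plus 1 on the log2 scale for 13 genes, 1 point per library, with a bar at each genotype's mean of the log2 values, heterozygous in blue and knockout in red. Afp stood at 3.46 and 3.32 FPKM in the heterozygous libraries against 252 and 299 in the knockout libraries, while Krt7, Spp1 and Cldn6 lay lower in the knockout.

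The oxygen-sensing pathway was compared because Hif1an, also called FIH1, limits the activity of hypoxia-inducible factor (HIF), and HIF drives the angiogenic factor Vegfa. Hif1an rose 3.43-fold, from 11.1 ± 0.822 to 38.2 ± 3.41 FPKM (SD, n = 2) (log2 change 1.69 ± 0.19 SE, limma adjusted p = 0.00367). Of 37 measured HIF target genes, 15 fell and 0 rose, and 20 were lower when adjusted over the list alone. Their median log2 change was -0.83 (camera adjusted p = 6.91e-09, and adjusted p = 0.617 with an estimated correlation). Plod2, which hydroxylates collagen lysines, fell from 19.6 ± 4.69 to 1.23 ± 0.0464 FPKM, and Vldlr, a lipoprotein receptor, from 18.3 ± 2.27 to 1.18 ± 0.506 FPKM. Ak4, a mitochondrial adenylate kinase, fell from 6.36 ± 0.367 to 0.159 ± 0.05197 FPKM and Pdk1, which inhibits pyruvate dehydrogenase, from 39.4 ± 4.801 to 6.11 ± 0.336 FPKM. Among HIF pathway regulators, Egln3 and Egln1, prolyl hydroxylases that mark HIF for degradation, fell from 4.46 ± 0.267 to 0.478 ± 0.118 FPKM and from 36.8 ± 5.53 to 19.2 ± 1.43 FPKM. Hif1an was the 1 member of 14 that rose (camera adjusted p = 0.871). Hif1a itself stood at 102 and 105 FPKM against 69.1 and 78.6 FPKM and did not pass the threshold (limma adjusted p = 0.152). Vegfa, the main growth factor of endothelial cells, fell 1.98-fold, from 55.4 ± 3.22 to 27.9 ± 0.962 FPKM (limma adjusted p = 0.0209), at 57.6 and 53.1 FPKM against 28.6 and 27.2 FPKM. Other pro-angiogenic factors went both ways, with 4 of 24 higher and 4 lower, 4 and 6 when adjusted over the list alone (camera adjusted p = 0.0989). Spp1 and Efna1, an ephrin, fell, the latter from 25.8 ± 6.78 to 5.58 ± 2.67 FPKM. Angpt2, a ligand of the endothelial receptor Tie2, rose from 0.336 ± 0.132 to 4.304 ± 0.974 FPKM and the chemokine Ccl2 from 7.63 ± 2.23 to 27.7 ± 3.75 FPKM. Of 12 anti-angiogenic factors, 4 rose and 2 fell, 4 and 6 when adjusted over the list alone, with a median log2 change of -0.33 (camera adjusted p = 0.781). The metalloproteinase inhibitor Timp3 rose from 2.56 ± 0.319 to 61.1 ± 1.22 FPKM and Adamts1 from 3.79 ± 0.839 to 12.3 ± 1.19 FPKM, while Sema3f, a repulsive semaphorin, fell from 9.96 ± 1.002 to 1.12 ± 0.202 FPKM. Without heterozygous replicate 1 or 2, the log2 change was 1.62 or 1.76 for Hif1an and -0.90 or -1.02 for Vegfa, but both calls were lost. Most calls of the HIF target genes, the regulators and the pro-angiogenic and anti-angiogenic genes were lost there as well. The median log2 change of the HIF target genes was -0.53 without knockout replicate 2.

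**Figure D3:**
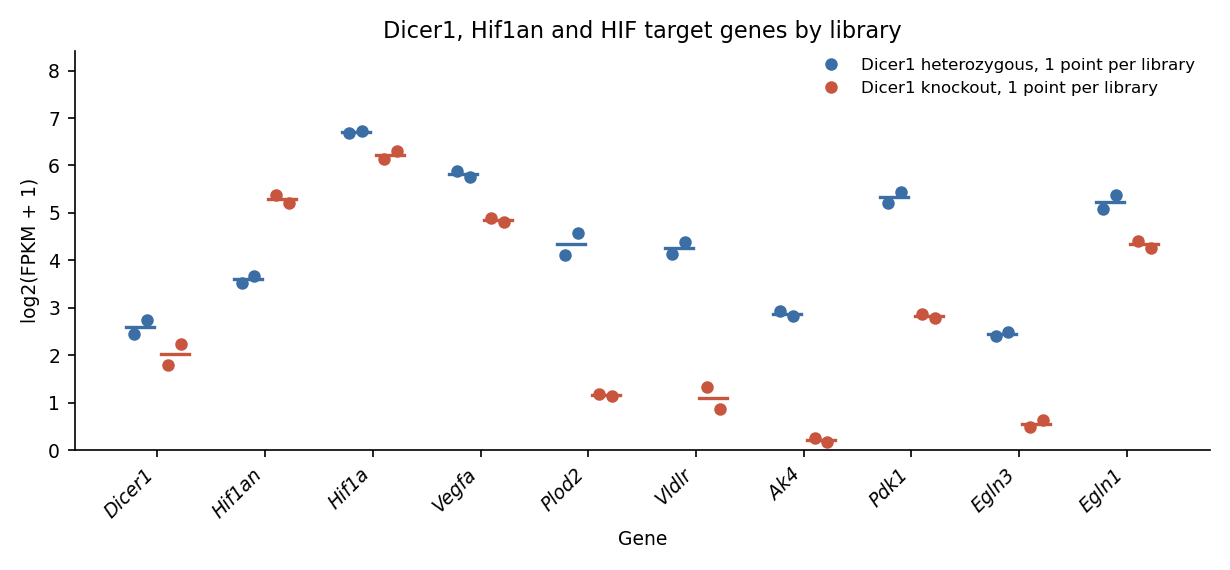
FPKM plus 1 on the log2 scale for Dicer1, Hif1an, Hif1a, Vegfa and 6 genes of the HIF lists, 1 point per library, with a bar at each genotype's mean of the log2 values, heterozygous in blue and knockout in red. Hif1an is higher in both knockout libraries, at 40.6 and 35.8 FPKM against 10.6 and 11.7, and Plod2, Vldlr, Ak4 and Pdk1 are lower in both.

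Known targets of the miRNAs lost from the knockout library were compared next with the question whether they were higher. Of 30 let-7 targets, 12 rose and 3 fell, 15 and 3 when adjusted over the list alone (camera adjusted p = 0.00528, and adjusted p = 0.594 with an estimated correlation). Nr6a1, an orphan nuclear receptor of early development, rose from 2.71 ± 0.0852 to 26.5 ± 0.553 FPKM (SD, n = 2), and Arid3a from 0.501 ± 0.1004 to 9.65 ± 0.108 FPKM. Igf2bp3, an oncofetal RNA-binding protein, rose from 2.54 ± 0.326 to 15.1 ± 4.27 FPKM and Arid3b from 1.17 ± 0.03499 to 7.45 ± 0.865 FPKM. Hmga2, a textbook let-7 target, stood at 200.1 and 203 FPKM against 128 and 166 FPKM and did not pass the threshold (limma adjusted p = 0.2195). Of 26 miR-29 targets, 11 rose and 2 fell, 16 and 2 when adjusted over the list alone (camera adjusted p = 5.95e-05, and adjusted p = 0.594 with an estimated correlation). They included Dnmt3a, a DNA methyltransferase, which rose from 5.17 ± 1.06 to 15.7 ± 0.367 FPKM, and Tet3, which oxidises methylcytosine, from 3.42 ± 0.141 to 9.96 ± 0.433 FPKM, while the laminin chain Lamc2 fell from 34.8 ± 0.256 to 11.9 ± 0.387 FPKM. With no filter on low values the median of the miR-29 targets was 0.48 in place of 0.74. Target lists of the other families did not pass the threshold. For miR-21, the highest miRNA of the heterozygous library, 6 of 23 targets rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0966). Timp3, the MAPK inhibitor Spry1 and Btg2 were among those that rose. The counts were 3 higher and 3 lower of 28 for miR-17 and miR-20, 4 and 4 when adjusted over the list alone (camera adjusted p = 0.6896) and 3 and 5 of 21 for miR-15 and miR-16, 5 and 6 when adjusted over the list alone (camera adjusted p = 0.871). Over all genes and also when adjusted over the list alone they were 3 and 4 of 23 for miR-34 (camera adjusted p = 0.988) and 2 and 2 of 23 for miR-200 (camera adjusted p = 0.995). Targets that fell included the cyclins Ccnd1, from 273 ± 9.001 to 112 ± 10.3 FPKM, and Ccnd2, from 22.02 ± 1.29 to 5.28 ± 0.672 FPKM, while the third D cyclin, Ccnd3, rose from 24.3 ± 1.01 to 67.9 ± 17.7 FPKM. Genes of the miRNA pathway itself rose in 6 of 25 cases with 0 lower, and 8 were higher when adjusted over the list alone (camera adjusted p = 0.0116, and adjusted p = 0.617 with an estimated correlation). Among them were the silencing scaffold Tnrc6a, from 14.7 ± 0.352 to 48.3 ± 1.17 FPKM, the decapping enzyme Dcp2, from 7.69 ± 0.0993 to 20.2 ± 0.782 FPKM, Tnrc6b and Mov10. Without heterozygous replicate 1 and 2, 3 and 2 of the 15 let-7 targets, 1 and 1 of the 7 miR-21 targets, 1 and 1 of the 8 for miR-15 and miR-16 and 1 and 1 of the 7 for miR-34 stayed past the threshold, and 0 of the 13 miR-29 targets, of the 6 miRNA pathway genes, of the 6 for miR-17 and miR-20 and of the 4 for miR-200. Without knockout replicate 2, 7 of the 13 miR-29 targets, 4 of the 6 for miR-17 and miR-20, 1 of the 4 for miR-200 and 3 of the 6 miRNA pathway genes stayed.

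Interferon-stimulated genes formed another group that was higher. Of 26 measured members, 13 rose and 0 fell, and 16 were higher when adjusted over the list alone. The median log2 change was 1.01 (camera adjusted p = 3.08e-08, and adjusted p = 0.594 with an estimated correlation). That median was 0.53 with a pseudocount of 5 and 0.58 with no filter on low values. Ifi27l2a rose from 1.27 ± 0.806 to 23.1 ± 3.26 FPKM (SD, n = 2) and Usp18, which removes the ubiquitin-like ISG15, from 0.177 ± 0.189 to 5.44 ± 1.26 FPKM. The immunoproteasome subunit Psmb8 rose from 0.194 ± 0.106 to 2.85 ± 0.583 FPKM and Parp14 from 1.26 ± 0.256 to 5.87 ± 0.682 FPKM. Ifitm3, which is interferon-induced but stood outside the list, fell from 43.9 ± 3.92 to 1.89 ± 1.15 FPKM. Of 12 antigen presentation genes, 3 rose and 0 fell, 6 higher when adjusted over the list alone (camera adjusted p = 0.0132, and adjusted p = 0.617 with an estimated correlation). They were Psmb8, the peptide transporter Tap2, from 1.26 ± 0.633 to 4.18 ± 0.01204 FPKM, and the class I gene H2-T23, from 1.38 ± 0.322 to 4.17 ± 0.734 FPKM. Of the 13 interferon-stimulated genes, 2 stayed past the threshold without heterozygous replicate 1 and 2 without heterozygous replicate 2, and 0 of the 3 antigen presentation genes did in either case. Of these 3, 1 stayed without knockout replicate 1 and 2 without knockout replicate 2, and the antigen presentation list lost its call with a mean FPKM of at least 5 (camera adjusted p = 0.208).

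By camera at the preset correlation, lists of the cell cycle were higher and lists of ribosomal proteins and oxidative phosphorylation lower in the knockout. By fry, described below, these lists did not pass the threshold. Of 30 G1/S genes, 1 rose, the histone chaperone Chaf1b, from 16.9 ± 0.519 to 32.05 ± 7.01 FPKM (SD, n = 2). Of the same 30 genes, 12 were higher when adjusted over the list alone (median log2 change 0.59, camera adjusted p = 5.95e-05, and adjusted p = 0.6604 with an estimated correlation). Of 30 G2/M genes, 4 rose and 0 fell, 4 higher also when adjusted over the list alone (camera adjusted p = 0.000137, and adjusted p = 0.617 with an estimated correlation). They were the phosphatase Cdc25b, from 38.2 ± 5.01 to 94.3 ± 20.7 FPKM, cyclin Ccna2, from 64.8 ± 15.4 to 131 ± 13.1 FPKM, the spindle protein Nusap1 and the kinase Aurka. Cytosolic ribosomal proteins had a median log2 change of -0.70, with 57 of 58 below 0 (camera adjusted p = 8.68e-11, and adjusted p = 0.623 with an estimated correlation). Of the 58, 3 passed the threshold by limma, 0 when adjusted over the list alone and 29 at an unadjusted p under 0.05. The 3 were Rplp1, from 1994 ± 297 to 744 ± 125 FPKM, Rplp0, from 2128 ± 186 to 832 ± 201 FPKM, and Rpl22, from 144 ± 1.97 to 83.7 ± 4.05 FPKM. Of 42 oxidative phosphorylation genes, 0 passed the threshold by limma, 0 when adjusted over the list alone and 10 at an unadjusted p under 0.05. Their median log2 change was -0.30 (camera adjusted p = 0.0121, and adjusted p = 0.731 with an estimated correlation). After quantile normalization the median of ribosomal proteins was -0.31 (cytosolic ribosomal proteins, camera adjusted p = 0.0043). Without that step it was -0.91 in knockout replicate 2, the library with 18.5% of its FPKM sum in small RNA models, and -0.46 in knockout replicate 1. Without knockout replicate 2 the adjusted p was 0.351 for oxidative phosphorylation genes (median -0.16) and 2.66e-08 for ribosomal proteins, and without heterozygous replicate 2 that of oxidative phosphorylation genes was 0.0606 (median -0.20). Without knockout replicate 1 their median was -0.47. Chaf1b, the 4 G2/M genes and the 3 ribosomal genes were no longer past the threshold without either heterozygous replicate. Nor was Chaf1b without knockout replicate 1, or the 3 ribosomal genes without knockout replicate 2, and 1 and 2 of the 4 G2/M genes stayed without knockout replicate 1 and 2.

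Markers of cell identity were compared between the genotypes. Of 17 measured markers of gastric and other endodermal identity known from lung tumours, 10 rose and 2 fell, 12 and 2 when adjusted over the list alone (median log2 change 1.63, camera adjusted p = 1.46e-06, and adjusted p = 0.594 with an estimated correlation). That median was 0.80 with a pseudocount of 5, 1.06 with no filter on low values and 1.04 without genes listed at 0. It was 2.24 with a mean FPKM of at least 5. Beside Afp and Apob the list included Lgals4, from 25.6 ± 2.76 to 405 ± 136 FPKM (SD, n = 2), and the microvillus protein Vil1, from 1.27 ± 0.159 to 29.1 ± 6.31 FPKM. Hnf4a, a transcription factor of liver and gut, rose from 4.54 ± 0.385 to 47.4 ± 6.19 FPKM. Epithelial markers fell in 8 of 23 cases and rose in 2, 8 and 4 when adjusted over the list alone (camera adjusted p = 0.0222, and adjusted p = 0.731 with an estimated correlation). Krt7 and the claudin Cldn7 fell, the latter from 13.7 ± 0.699 to 1.62 ± 0.905 FPKM. Rab25 stood at 7.74 and 5.45 FPKM against 0 and 0.167 FPKM, and Krt20, a keratin of gut epithelium, rose from 1.27 ± 0.448 to 40.8 ± 3.85 FPKM. Mesenchymal markers also fell, in 6 of 18 cases with 2 higher, 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0303, and adjusted p = 0.617 with an estimated correlation). S100a4 fell from 1045 ± 175 to 172 ± 47.2 FPKM and the transcription factor Snai2 from 10.7 ± 0.277 to 2.66 ± 0.0972 FPKM. Of 5 measured fibroblast markers, 4 fell, also when adjusted over the list alone (camera adjusted p = 0.00104, and adjusted p = 0.617 with an estimated correlation), including the collagen VI chains Col6a1, from 46.00 ± 5.86 to 10.6 ± 2.43 FPKM, and Col6a2, from 16.8 ± 1.62 to 1.14 ± 0.4397 FPKM. Markers of alveolar type 2 cells, at 1 higher and 2 lower of 7, 1 and 4 when adjusted over the list alone, did not pass the threshold (camera adjusted p = 0.258), and 0 of these 3 genes stayed past it without either heterozygous replicate. Few markers of other cells passed the filter on low values, 4 of 18 club and ciliated cell markers with 0 past the threshold by limma and 3 at an unadjusted p under 0.05. The others were 2 of 19 endothelial markers, of which Flt1 fell, and 2 of 23 leukocyte markers, Cd68 and Cd14, which both fell. All 3 calls were lost without either heterozygous replicate, and without knockout replicate 2 those of Flt1 and of 1 of the 2 leukocyte genes. The list call for mesenchymal markers was lost without heterozygous replicate 1 (camera adjusted p = 0.0653), knockout replicate 1 (camera adjusted p = 0.0905) or knockout replicate 2 (camera adjusted p = 0.0626), and that for epithelial markers without knockout replicate 2 (camera adjusted p = 0.156). With a mean FPKM of at least 5, quantile normalization and camera on ranks, the adjusted p was 0.251, 0.0705 and 0.0524 for epithelial and 0.0745, 0.0586 and 0.0524 for mesenchymal markers. It was 0.217 for epithelial markers without genes listed at 0. With no filter on low values it was 0.133 for mesenchymal markers and 0.133 for fibroblast markers, whose median was then -0.12 in place of -2.03. The epithelial median was -0.74 and -0.19 without knockout replicate 1 and 2, and the mesenchymal median -0.57 without heterozygous replicate 2 and -0.62 without knockout replicate 1. Without heterozygous replicate 1 or 2, 9 and 9 of the 12 endodermal genes, 6 and 5 of the 10 epithelial genes, 1 and 1 of the 8 mesenchymal genes and 2 and 1 of the 4 fibroblast genes stayed past the threshold.

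**Figure D4:**
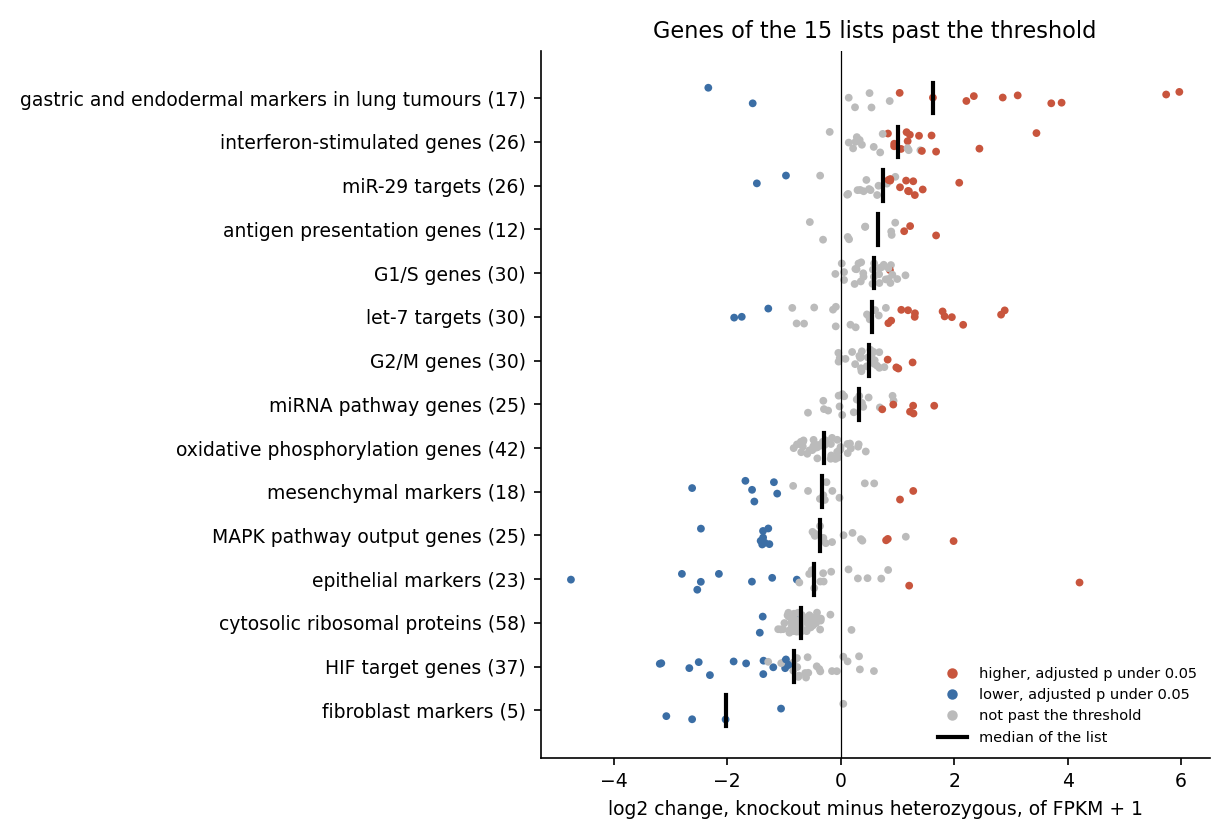
log2 change of FPKM plus 1, knockout minus heterozygous, for each tested gene of the 15 lists past the camera threshold, with the number of tested genes beside each name, red for genes higher and blue for genes lower at an adjusted p under 0.05, grey for the others, and a black bar at each list's median. The median of HIF target genes lies at -0.83 and that of the gastric and endodermal markers at 1.63.

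Kras, Trp53 and lists of MAPK output genes and of p53 targets and CDK inhibitors were compared last. The tumours arose in animals without p53, so changes in the list of p53 targets cannot be read as p53 output. Kras stood at 27.7 ± 1.72 against 31.7 ± 6.25 FPKM (SD, n = 2, limma adjusted p = 0.627), with 26.5 and 28.95 against 27.3 and 36.1 by library. Trp53, the gene of p53, stood at 1.94 and 2.32 FPKM against 1.46 and 0.747 FPKM (limma adjusted p = 0.2098). Output genes of the MAPK pathway fell in 8 of 25 cases and rose in 3, 8 and 4 when adjusted over the list alone (camera adjusted p = 0.0347, and adjusted p = 0.623 with an estimated correlation). The EGF receptor ligand Areg fell from 49.5 ± 11.4 to 8.52 ± 4.24 FPKM, the phosphatase Dusp4 from 40.5 ± 0.598 to 14.7 ± 2.06 FPKM and Ier3 from 314 ± 20.4 to 120.5 ± 17.4 FPKM, while Spry1 rose from 1.73 ± 0.153 to 10.03 ± 2.76 FPKM. The proto-oncogene Myc, also of this list, fell from 51.2 ± 2.72 to 19.2 ± 0.466 FPKM. The MAPK list lost its call without heterozygous replicate 1 (camera adjusted p = 0.0772), knockout replicate 1 (camera adjusted p = 0.114) or knockout replicate 2 (camera adjusted p = 0.0596), with a pseudocount of 0.1 (camera adjusted p = 0.0511) and by camera on ranks (adjusted p = 0.0561), and 0 of its 11 genes stayed past the threshold without either heterozygous replicate. Of 25 p53 targets and CDK inhibitors, 3 rose and 4 fell, 4 and 5 when adjusted over the list alone (camera adjusted p = 0.496), with Btg2 from 10.7 ± 0.684 to 31.2 ± 2.72 FPKM and the CDK inhibitor Cdkn2b from 86.4 ± 2.196 to 33.8 ± 2.69 FPKM. Without either heterozygous replicate 0 of these 7 genes stayed past the threshold, and 4 and 2 without knockout replicate 1 and 2. Over all 35 lists tested, 15 passed the camera threshold with the preset correlation and 0 with an estimated correlation. By fry 6 lists passed, 5 of them among the 15. The fry method tests whether the genes of a list move on balance in one direction. Those 5 were the let-7 and miR-29 targets, interferon-stimulated genes, gastric and endodermal markers and antigen presentation genes. The fry adjusted p was 0.14 for G1/S genes, 0.110 for G2/M genes, 0.132 for ribosomal proteins and 0.287 for oxidative phosphorylation genes. It was 0.14 for epithelial, 0.0714 for mesenchymal and 0.0583 for fibroblast markers. For MAPK output, miRNA pathway and HIF target genes it was 0.0762, 0.0597 and 0.0672.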

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

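Leaving out small and unnamed gene models, genes listed at 0 or the glycolysis enzymes of the HIF list were alternatives chosen after seeing the data. The count of 1551 changed genes ranged from 290 to 1869 when single libraries were left out, where limma assumes that the lone library varies like the other genotype's, and the low counts came without heterozygous replicate 1 (290) or 2 (299). Without either heterozygous replicate the variance within groups came from the knockout pair alone. The median absolute log2 difference between replicates was 0.32 in that pair against 0.17 in the heterozygous pair. Calls lost there therefore reflect that spread as well as the library left out. A limit of 0.01 on the adjusted p gave 526 genes. The other 13 alternatives stayed within 1.5 times the main count, from 1058 with a mean FPKM of at least 5 to 2182 with the replicate number as a block. Whether same-numbered libraries form pairs is not known. They deviated from their group means with a correlation of 0.0744, and 2 pairs do not settle it. The block left 15 lists past the threshold and 1547 of the 1551 genes called. Leaving out small and unnamed gene models gave 2091 genes and leaving out genes listed at 0 gave 2001, and the cause was not tested. The median log2 change of all tested genes lay between -0.049 with median centring and 0.051 without knockout replicate 2 under these alternatives.

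The number of lists past the threshold, 15, was 11 to 14 without single libraries, 0 with an estimated correlation, 6 by fry and 12 to 15 in the remaining alternatives. Of the 15 lists themselves, 5 kept their call by fry and 11 to 15 in the alternatives other than fry and the estimated correlation. HIF target genes, with a median log2 change of -0.83, lost their call with an estimated correlation (adjusted p = 0.617) and by fry (adjusted p = 0.0672), and had medians from -0.997 to -0.53 without single libraries. In the other 14 alternatives their adjusted p lay between 2.96e-10 and 6.11e-07, and without the glycolysis enzymes the median was -0.96. With a correlation estimated from 4 libraries, camera has 2 residual degrees of freedom, so a lost call by itself says little. Estimated correlations were 0.63 for ribosomal proteins, 0.47 for G1/S genes, 0.44 for oxidative phosphorylation genes and 0.32 for HIF target genes. The camera calls of these lists rest on the preset 0.01, and fry did not call them. The let-7 and miR-29 targets, with estimated correlations of -0.018 and -0.021, lost their calls too. For these 2 lists a correlation between genes does not account for the loss. Of 127 genes chosen by the rule for named genes and past the threshold, 45 and 43 stayed past it without heterozygous replicate 1 and 2, 112 and 98 without knockout replicate 1 and 2, and 0 of them reversed in the 10 alternatives run for them, the others not having been tabulated gene by gene. In the 6 alternatives that keep every library, 7 calls of these genes were lost. The share of mature miRNAs at least 4-fold lower was 100% with a minimum of 10 or 1000, and so were the shares at least 2-fold and at least 10-fold lower. For hairpins it was 21.3% with a minimum of 10, 58.8% with a minimum of 1000 and 61.4% at a 2-fold limit, against 45.8%, and 37.3% at a 10-fold limit, and the cause was not tested. Scaling the small RNA libraries to miRNAs that do not need Dicer1 was not run, since mir-451a stood at 0 against 8. The shift of mRNAs by 7-mer sites in 3' UTRs was not analysed here, since it needs transcript sequences. The totals of the small RNA libraries are not known, so neither is what their depth can show.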

Other observations

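Several of the preset groups were not part of the comparisons above. Of 28 genes of the unfolded protein response and ATF4, 4 rose and 7 fell, 7 and 12 when adjusted over the list alone (camera adjusted p = 0.1805). The kinase-like Trib3 fell from 28.6 ± 9.05 to 4.59 ± 0.4502 FPKM (SD, n = 2), asparagine synthetase Asns from 169 ± 25.5 to 61.1 ± 11.8 FPKM and Aldh18a1, of proline synthesis, from 70.7 ± 8.19 to 23.2 ± 7.52 FPKM. The chaperone Dnajb9 rose from 7.03 ± 0.761 to 21.1 ± 7.66 FPKM. Of 10 imprinted genes, 5 rose and 0 fell (camera adjusted p = 0.0748, fry adjusted p = 0.0179), among them Igf2r, from 37.7 ± 1.92 to 80.7 ± 5.69 FPKM, and Grb10, from 0.949 ± 0.361 to 3.68 ± 0.327 FPKM. Apoptosis regulators were 5 higher and 1 lower of 24 (camera adjusted p = 0.495), with the BH3-only genes Bmf, from 7.76 ± 2.27 to 40.8 ± 8.78 FPKM, and Bcl2l11, from 5.84 ± 0.3402 to 15.9 ± 1.58 FPKM, both higher. Aldh3a1, an aldehyde dehydrogenase of the NRF2 list, fell from 161 ± 5.09 to 12.7 ± 3.84 FPKM, in a list with 1 higher and 2 lower of 21 (camera adjusted p = 0.577). Without heterozygous replicate 1, 0 of the 11 UPR and ATF4 genes, 0 of the 5 imprinted genes, 1 of the 6 apoptosis genes and 1 of the 3 NRF2 genes stayed past the threshold, and without heterozygous replicate 2 the numbers were 1, 0, 0 and 1. Without knockout replicate 2, 3 of the 11 UPR and ATF4 genes, 1 of the 5 imprinted genes and 4 of the 6 apoptosis genes stayed.

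The other lists did not pass the camera threshold or had too few members for it. Collagens and matrix crosslinkers were 3 higher and 5 lower of 18, 7 and 7 when adjusted over the list alone (camera adjusted p = 0.496), NF-kB targets and cytokines 4 higher and 6 lower of 27 (camera adjusted p = 0.285). The chemokine Ccl20 rose from 1.11 ± 0.594 to 10.2 ± 1.63 FPKM. TGF-beta response genes were 2 higher and 1 lower of 24 (camera adjusted p = 0.496), and the receptor Tgfbr1 rose from 8.11 ± 0.269 to 31.1 ± 7.05 FPKM. Immediate early and stress genes were 3 higher and 1 lower of 19, 5 and 2 when adjusted over the list alone (camera adjusted p = 0.177), and Ier2 rose from 26.3 ± 2.07 to 78.3 ± 5.22 FPKM. Neuronal and axon guidance genes were 5 higher and 3 lower of 24, 5 and 6 when adjusted over the list alone (camera adjusted p = 0.496), cholesterol synthesis genes 1 higher and 0 lower of 22 (camera adjusted p = 0.1805), where Hsd17b7 rose, 0 when adjusted over the list alone. Of 22 histone genes of the replication type, 3 were measured, and Hist1h1c rose. The counts of NF-kB, TGF-beta, imprinted, apoptosis and NRF2 genes did not change when adjusted over the list alone. Without heterozygous replicate 1 and 2, 2 and 2 of the 8 collagen genes, 2 and 2 of the 10 NF-kB genes and 0 of the 8 neuronal genes stayed past the threshold, and 6 of the 10 NF-kB genes, 5 of the 8 collagen genes and 5 of the 8 neuronal genes without knockout replicate 2. The calls of Hsd17b7 and Hist1h1c were lost without any 1 of the 4 libraries. Those of the 3 TGF-beta and 4 immediate early genes were all lost without either heterozygous replicate, and 2 of the 3 TGF-beta genes stayed without knockout replicate 2. Median, mean and camera direction differed in sign for the lists of anti-angiogenic factors, HIF pathway regulators, NRF2 targets and the miR-15 and miR-16, miR-34 and miR-200 targets.

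In the 3 paragraphs that follow, the tests of adult liver RNA, of intestine RNA as the source of the Apob level, of the cell line, of short transcripts and of both explanations for 5p arms were chosen only after the result was seen. The genotype, the biological explanation that the design gives, splits the libraries as the line code does and was not tested apart from it.

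Some liver and endoderm genes, among them Afp, Apob, Alb and Ttr, were higher in the knockout libraries, while no list of liver genes was tested and Cyp2e1, a liver enzyme, stood at 0.557 and 0.583 against 0 and 0.312 FPKM. Adult liver RNA as the source is argued against, since Afp at 275 FPKM stood above Alb at 34.4 FPKM and 6 of 20 genes abundant in liver reached 1 FPKM in the knockout mean, 6 of 15 without the 5 listed at 0 in every library, whose 0 can be a failed estimate. Fetal liver RNA, which carries erythroid transcripts, is argued against by 5 of 11 erythroid genes alone, since the other 6, globins among them, were listed at 0 in every library, and 0 of these 5 reached 1 FPKM, Slc4a1 standing at 0.0264 and 0.02203 FPKM. Intestine RNA remained open at a trace level, with 4 of 15 genes at 1 FPKM or more (4 of 9 without the 6 listed at 0 in every library) against 3 in the heterozygous mean, but not as the source of Apob at 86.5 FPKM, since the highest gene of that list, Rbp2, stood at 4.46 FPKM, below its heterozygous 8.59 FPKM. A difference between the cell lines apart from Dicer1 cannot be told apart from the genotype, with 1 line code per genotype, and a change of identity in the cells themselves stays a hypothesis.

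Ribosomal protein mRNAs were lower in the knockout libraries, with 57 of 58 below 0. With knockout replicate 1 alone the median was -0.46 (95% bootstrap interval over genes -0.55 to -0.40), beyond -0.35, which is 1 / 2 of the value over both. This goes against knockout replicate 2 as the only source in these libraries. The interval resamples genes that move together (estimated correlation 0.63) within 1 knockout library, so it carries no spread between libraries. A lower yield of short transcripts may account for part of the pattern, since 21 oxidative phosphorylation genes of small subunits, whose mRNAs are short too, had a median of -0.50 (95% bootstrap interval -0.67 to -0.15) and 8 genes of large subunits one of -0.17. The interval of the small subunits, also one over genes, spans -0.35, so the size of this part is not settled. A response of the cells to the loss of Dicer1 stays open as well.

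The mature miRNA values left in the knockout library lay mostly on 5p arms, since of the miRNAs with at least 100 in the heterozygous library, 22 of 33 5p arms stood above 0 in the knockout library and 0 of 19 3p arms, and over all mature miRNAs 41 of 162 and 2 of 147. The 5p arms at 100 or more kept 0.399% of their heterozygous sum, and reads of the heterozygous library carried into the knockout library are argued against, since they would leave the same share on 3p arms, a sum of 28.2 over the 9 3p arms expected at 1 or more, and these sum to at most 4.50 with each 0 raised to a rounding limit of 0.5. Reads from the 5' end of hairpins that were not cut may account for the values. Over the 33 5p arms, the knockout mature value followed the knockout hairpin value at a given heterozygous mature value (partial Spearman rho 0.605, 95% bootstrap interval 0.270 to 0.805, permutation p = 0.00025, two-sided, miRNAs not being independent replicates). Of the 22 arms above 0, 14 had a hairpin sum higher in the knockout library and 8 a lower one, among them mir-21a at 347686 against 20317 and mir-221 at 265 against 101, and reads counted in both tables would give such a relation too, so this stays a hypothesis.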
